A study of Homo sapiens with 26 samples.

How the data were processed

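The series measured RNA near the plasma membrane of HEK293T cells by APEX-seq. HEK293T is a human embryonic kidney line that carries the SV40 large T antigen. APEX2 is an engineered ascorbate peroxidase that, given hydrogen peroxide, turns biotin-phenol into short-lived radicals that tag nearby molecules. Per the labels' protocols, cells stably expressing APEX2 fusions were given biotin-phenol for 30 min and 1 mM hydrogen peroxide for 1 min, the reaction was quenched, RNA was taken up in TRIzol, and biotinylated RNA was pulled down on streptavidin beads and made into Illumina libraries. The labels list the same biotin-phenol and peroxide steps for the control samples. Which step was left out of the unlabeled controls was not given in the sources used here, nor was the strandedness of the libraries. Reads from genes that overlap on opposite strands therefore cannot be told apart, and such overlaps are stated beside the genes named.

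The deposited values are log2 FPKM (fragments per kilobase of exon, scaled to library size) for 25745 Ensembl genes in 26 libraries, running from -9.73 to 14.8. Per the submitters' processing notes, reads were aligned to hg38 with HISAT2 2.1.0, and edgeR was named without a version. Gene identifiers were matched to GENCODE 29 on hg38, the source of the symbols and coordinates given here. Of the identifiers, 24075 matched with their version, 1578 without it and 92 did not match.

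Read depth was recovered from the values. In 3956 genes at least 2 libraries shared the lowest value, and these floors gave a prior count close to 1.00 read scaled to library size. Undoing it gave reads for 25664 genes, whole to within 0.05 read for at least 99.9% of values in the genes with a shared floor and for 96.8% to 97.9% of values under 100 reads in the others. Recovered totals were 19.99 to 35.57 M (1e6) reads in the 14 libraries of the inside constructs and 11.6 to 16.62 M in the 12 libraries of the outside constructs. Depth and side of the membrane are therefore confounded. Intervals and floors from read numbers cover counting error only.

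Groups were taken from the sample titles, as 4 constructs each with labeled and control libraries, 4 and 4 for Lyn11 and 3 and 3 for the others. The series' design text calls them biological replicates. Replicate pairs within groups were compared by chi-square on genes with at least 20 reads summed over the pair. The 30 pairs gave 6.03 to 101 per gene, far above sampling noise, and their log2 values correlated at Pearson 0.745 to 0.967 across genes, which are not independent replicates, so no library was treated as a duplicate.

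The 22284 genes with a log2 value above 0 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 on the log2 values. The fit had a mean for each group, an intensity trend in the spread and 18 residual degrees of freedom, 20.87 after moderation. Values already carry the authors' prior count, so no other pseudocount was added, and differences of genes with few reads are understated. Tests were two-sided, with Benjamini-Hochberg adjustment within each of 10 comparisons and calls at an adjusted p under 0.05. These were labeled against control in each construct, the average of the 4 differences, the inside and the outside average, inside minus outside, Lyn11 minus Lck, and CD28 minus PDGFR. Errors after ± are standard errors of the fit, and SD is given by name. The 32 gene lists, with 1130 measured members, covered proteins by compartment and complex, RNA classes, stress and signalling responses, and markers of other cell types (blood, fibroblast, epithelial carcinoma). They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists with at least 5 measured members. The estimated correlation and limma's fry, which asks whether a list moves one way and does not compare it with other genes, were alternatives. List counts adjusted over the list alone are given beside those over all genes.

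Simulated data on the same genes, with 100 genes changed by 1 and 100 by 2 log2 units, tested the fit. It recovered 74% of the 2-unit changes for Lyn11, 61% for Lck, 70% for CD28 and 77% for PDGFR, with 0, 0, 39 and 271 false calls. The outside constructs draw the false calls because the fit pools the spread over all libraries and theirs is wider. The simulated list change was found with 0 other lists called. Genes were drawn independently of each other there, so false list calls from correlation between genes could not appear. An added fit that weighted the libraries by construct (weights 0.993 for Lyn11, 2.65 for Lck, 0.632 for CD28 and 0.602 for PDGFR), chosen after seeing the data, gave 6, 8, 3 and 2 false calls.

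Named genes followed a rule. For each construct, the average and inside minus outside, these were the 10 largest and 10 smallest log2 differences among genes with an adjusted p under 0.05, a mean log2 of at least 1, a symbol, and no overlap between labeled and control libraries. For the average all 4 constructs had to share the sign, and for inside minus outside both inside differences had to lie beyond both outside ones. Added to these were the 2 to 4 members of each list with the smallest adjusted p, up to 20 genes called in all 4 constructs, and a fixed set that included LYN, LCK, CD28, PDGFRA, PDGFRB, MALAT1, NEAT1, ACTB, GAPDH and MT-CO1. LCK was not found in the file by symbol. List members named beyond these, such as EGR3, ARC, GADD45B, DUSP1, KLF6 and ZFP36L1, were chosen after their values were seen, and not all of them were run under the alternatives.

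Reads of near-identical small RNA genes can be split between copies. They were therefore also summed over each of 14 families, as RPM (reads-per-million of the scaled library size), and tested by an exact permutation of labels within each construct (560000 relabelings, two-sided, adjusted over the families). This test, the 10-read filter, limma voom on the recovered reads, the removal of both low-complexity libraries and the construct weights were chosen after seeing the data. The groups, the comparisons, the lists, the rule for names and the other alternatives were set before the data were examined. Those were median centring, quantile normalization, a pseudocount of 1 FPKM, no filter, a stricter filter, library weights, a replicate block, each comparison on its own libraries, and each library left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the data, ran the permutations and drew the figures. Unmatched identifiers stayed in the tests and were not named by the rule. Fold changes against groups with 0 reads in every library use a floor of 3 reads over the group.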

Results

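RNA near the plasma membrane was profiled with APEX2 placed on the inner side by Lyn11 or Lck sequences, which come from lipid-anchored kinases, or on the outer side by CD28 or PDGFR sequences, which come from cell-surface receptors. Each construct had labeled libraries and unlabeled controls, and the design asks which RNAs labeling enriched and whether the sides differ. Lyn11 libraries held 22.39 to 26.14 M recovered reads when labeled and 23.2 to 35.57 M as controls. Lck libraries held 19.99 to 22.92 and 20.3 to 22.34 M, CD28 libraries 15.27 to 15.45 and 11.6 to 13.64 M, and PDGFR libraries 13 to 14.4 and 11.86 to 16.62 M. Spread around the group means differed as well, with residual SDs of 0.24 to 0.30 log2 units in Lck libraries and 0.63 to 0.96 in PDGFR libraries. CD28 labeled replicate 2 and PDGFR control replicate 2 stood apart, with 3147 and 3019 genes at 0 reads.

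The construct genes checked the labels in part. CD28, a T cell co-stimulatory receptor, had 1857 to 3591 reads in the 6 CD28 libraries and 0 to 1 in the 20 others (5.35 ± 0.39 against -6.52 ± 0.19 log2 FPKM, SD; exact permutation p = 4.34e-06). LYN, the Src-family kinase, was at 3.18 ± 0.27 in the 8 Lyn11 libraries and 3.06 ± 0.25 in the 18 others (SD; exact permutation p = 0.323). PDGFRB was higher in the 6 PDGFR libraries than in the 20 others (-1.41 ± 0.96 against -2.85 ± 0.72, SD; exact permutation p = 0.000269), with 9 to 58 against 2 to 38 reads. PDGFRA was lower in them (-3.02 ± 0.76 against -1.58 ± 0.38, SD; exact permutation p = 3.91e-05), with 9 to 44 against 23 to 148 reads. Adjusted over the 4 genes these p-values were 1.74e-05 for CD28, 0.323 for LYN, 0.000359 for PDGFRB and 7.82e-05 for PDGFRA. Reads of PDGFRB and PDGFRA overlapped between PDGFR libraries and the others, and those of CD28 did not overlap.

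With Lyn11, 7 of 13 measured spliceosomal RNAs and 6 of 33 immediate early mRNAs rose. EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315), a zinc finger transcription factor induced within minutes of growth factor stimulation, stood at 3.86 ± 0.28 log2 FPKM in 4 labeled libraries and -0.04 ± 0.30 in 4 controls (SD), with 884 to 1345 against 56 to 119 reads. Its log2 difference was 3.90 ± 0.38 (adjusted p = 5.7e-06), and FOS and FOSB, subunits of the AP-1 transcription factor, rose by 3.64 ± 0.57 and 2.15 ± 0.27. RNVU1-29 (chromosome 1, 146376807 to 146376970), a variant U1 gene, rose by 3.24 ± 0.27 (adjusted p = 1.1e-06), from 24 to 73 reads to 269 to 321. TXNIP (chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin, fell by 0.91 ± 0.13 (adjusted p = 0.000792).

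Of 22284 genes, 118 were higher and 11 lower with Lyn11. Among genes with a symbol and a mean log2 of at least 1, the other large rises were RNU1-1, RNU1-2, RNU1-4, RNU4-1, RNU4-2, RNVU1-4, RNVU1-22 and RNVU1-34, all spliceosomal RNA genes, at 3.14 to 3.36. ENSG00000270022, which has no symbol, rose by 4.12 ± 0.51 (adjusted p = 0.000108). Among the same genes, falls beside TXNIP were PRKACB-DT at -1.37 ± 0.29, EID2B at -1.004 ± 0.20, NCLP1 at -0.98 ± 0.20 and PAXIP1-DT at -0.75 ± 0.16. NCLP1 is a nucleolin pseudogene that lies opposite RABL6, and EID2B overlaps an antisense gene. PRKACB-DT, EID2B, NCLP1, PAXIP1-DT, RNVU1-4 and RNU4-1 each lost the call without labeled replicate 4 or without control replicate 2, 3 or 4, and were called in 31, 30, 33, 29, 20 and 29 of 38 alternatives (adjusted p up to 0.254, 0.106, 0.101, 0.259, 0.186 and 0.186). Adjusted over the list alone, 11 spliceosomal RNAs and 16 immediate early genes rose. Both lists were called, with an adjusted p of 9.28e-06 and 0.00838 with an estimated correlation. The number of genes called moved to 74 with a stricter filter and to 256 with quantile normalization.

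With Lck, 4 of 33 immediate early mRNAs, 6 of 13 measured spliceosomal RNAs and copies of U3 rose. EGR1 rose by 4.41 ± 0.44 (adjusted p = 1e-05), from 46 to 53 reads in 3 controls to 1032 to 1268 in 3 labeled libraries. FOS rose by 4.10 ± 0.66, FOSB by 2.90 ± 0.32 and CCN1, a secreted matricellular protein of the immediate early set, by 1.56 ± 0.27 (adjusted p = 0.00484). SNORD3B-2, a copy of U3, the nucleolar RNA that guides early cleavage of ribosomal RNA precursors, rose by 3.20 ± 0.34 (adjusted p = 1.35e-05). TXNIP fell by 1.01 ± 0.15 (adjusted p = 0.0013).

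In all, 169 genes were higher and 8 lower with Lck. RNVU1-34, RNU1-1, RNU1-4, RNU2-63P and RNU4-1 rose by 3.22 to 3.79, and RNU6-922P had 72 against 2 reads over the 3 libraries (34.1-fold, 95% interval 9.12 to 287). HM13-AS1 rose by 3.86 ± 0.79 and SMIM47 by 3.60 ± 0.84. Both lie opposite a coding gene, HM13 and ACP4, so their strand is open. PRKACB-DT at -1.79 ± 0.34, STK16P1 at -1.61 ± 0.27, which lies opposite POLE2, and CA3-AS1 at -0.89 ± 0.20 completed the falls named. HM13-AS1, SMIM47, RNU1-4, RNU2-63P, RNU4-1, PRKACB-DT and CA3-AS1 each lost the call without labeled replicate 1 or without control replicate 2 (adjusted p up to 0.107, 0.183, 0.0607, 0.138, 0.211, 0.122 and 0.254 over the alternatives), and RNU1-1 lost it with limma voom (adjusted p = 0.108, the highest over its alternatives). Adjusted over the list alone, 11 spliceosomal RNAs were up and immediate early genes were 12 up and 1 down, with an adjusted p of 7.13e-05 and 0.0332 with an estimated correlation. Lck libraries had the least spread, and weights by construct raised the count to 1831 genes (1200 higher, 631 lower). Quantile normalization gave 405 higher and 79 lower, or 83.7% higher against 95.5%.

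**Figure D1:**
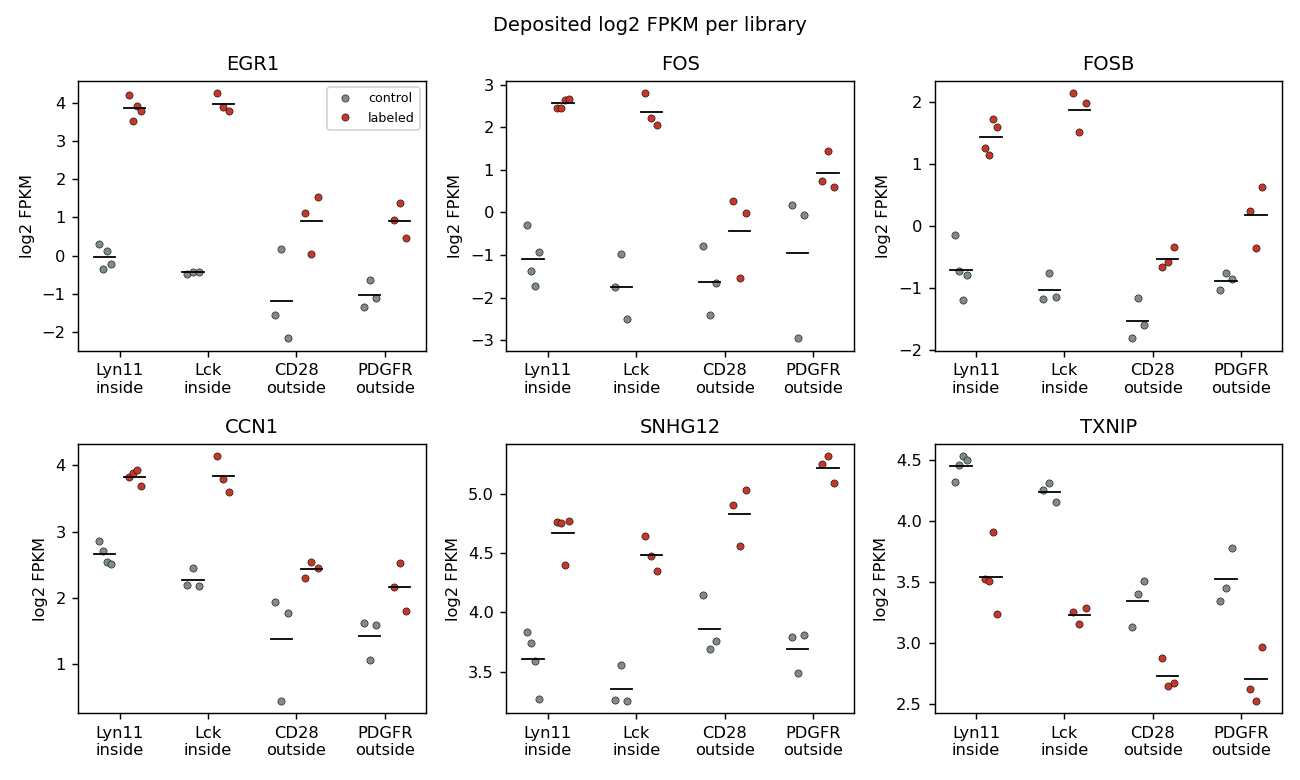
Deposited log2 FPKM of EGR1, FOS, FOSB, CCN1, SNHG12 and TXNIP in each of the 26 libraries, with labeled and control libraries of each construct side by side and a line at each group mean. EGR1 lies at 3.86 and 3.97 in labeled Lyn11 and Lck libraries on average, against 0.90 and 0.92 with CD28 and PDGFR. Control levels differ between constructs too, so these labeled levels alone do not give the difference between sides.

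With CD28, U1 genes rose, and a U6 copy, pseudogenes and antisense RNAs were among the falls. RNU1-2 had 84 reads over 3 labeled libraries and 1 over 3 controls (75.2-fold, 95% interval 13.1 to 3005), and RNU1-3 had 61 and 3 (18.2-fold, 5.94 to 90.7). RNU1-1 rose by 4.09 ± 0.59 (adjusted p = 0.002) and MIR5087, which lies within LINC01138, by 3.25 ± 0.43. RNVU1-3, RNVU1-15, RNVU1-21, RNVU1-29, RNVU1-34 and RNU1-28P rose by 1.89 to 2.58. SNHG12, a host gene of small nucleolar RNAs, rose by 0.97 ± 0.16 and ZFAS1, another host gene, by 0.65 ± 0.14 (adjusted p = 0.0365).

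There were 39 higher and 67 lower genes with CD28. RNU6-331P, a U6 copy opposite MTMR3, had 1 read in labeled libraries and 32 in controls (35.8-fold lower, 5.97 to 1455). RPL35AP16 fell by 3.48 ± 0.72, CREB3L2-AS1 by 2.38 ± 0.40, MIR3680-1, which lies within SMG1P3, by 2.09 ± 0.28, and ERVFRD-1, the envelope gene that encodes syncytin-2, by 1.45 ± 0.23. ERVFRD-1, CREB3L2-AS1 and RPL35AP16 lie opposite SMIM13, CREB3L2 and LARS. DUTP7, RPL35AP32, CNTFR-AS1, RPL7AP65 and ATP6V0CP1 fell by 1.42 to 1.78. EGR1 passed at 2.09 ± 0.44 (adjusted p = 0.0316) although its groups overlapped, with labeled replicate 2 at 0.05 and control replicate 2 at 0.16 log2 FPKM (45 and 43 reads), and lost the call with construct weights (adjusted p = 0.139, up to 0.726 over the alternatives). Spliceosomal RNAs had 3 members up, 12 adjusted over the list alone, called also with an estimated correlation (adjusted p = 0.00102).

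The CD28 count rests on the spread shared with the tighter inside libraries. Simulated data without a change in most genes gave 39 false calls, and construct weights left 15 genes (8 higher, 7 lower). Limma voom on all libraries called 21 of 25597 genes. Limma on the CD28 libraries alone called 0, with 1525 genes at an unadjusted p under 0.05. That fit recovered 26% of simulated 2-unit changes and 1% of 1-unit changes, against 70% and 37% with all libraries, so its 0 does not show which calls are false. RNU1-2, RNU1-1, MIR5087, RNVU1-15, CREB3L2-AS1 and MIR3680-1 were among the 15 (adjusted p = 0.00984 to 0.029), while SNHG12 at 0.111, RNVU1-29 at 0.0962 and ERVFRD-1 at 0.0508 were not (up to 0.545, 0.31 and 0.538 over the alternatives). DUTP7 and ZFAS1 were called in 12 and 24 of 38 alternatives. The split was 36.8% higher, against 51.9% with median centring (55 higher, 51 lower) and 58.7% with quantile normalization (37 and 26). Median centring moved the median difference of all genes from 0.03 to 0.15.

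With PDGFR, U1, U4 and U3 genes rose. RNU4-2 (chromosome 12, 120291763 to 120291903) rose by 5.74 ± 0.64 (adjusted p = 4.35e-05), from 0 to 12 reads in 3 controls to 87 to 111 in 3 labeled libraries. RNU1-1 (chromosome 1, 16514122 to 16514285) had 0 reads in every control and was at least 31.1-fold higher. RNVU1-29 rose by 3.94 ± 0.32 (adjusted p = 8.72e-07) and SNHG12 by 1.53 ± 0.16 (adjusted p = 3.66e-05). SNORD3C, a U3 copy, rose by 3.58 ± 0.60.

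There were 306 higher and 169 lower genes. RNVU1-18, RNU4ATAC, RNVU1-4, TAF9P3, RNU4-1 and RNVU1-31 rose by 3.95 to 4.37, MIR93, which lies within MCM7, was at least 15.7-fold higher, and RNU5A-8P had 51 against 2 reads (26.7-fold, 95% interval 7.02 to 226). RNU4ATAC lies opposite CLASP1, and the summed U4atac reads differed by only 0.025 with PDGFR. RNU6-122P, which lies within XIAP, was at least 24.8-fold lower. MIR548AQ, MIR2052, RNA5SP219, AC008115.3, RNU6-681P, RNU7-128P and MIR3165 had differences of -4.08 to -3.10, and RNU6-142P (17.5-fold, 5.69 to 87.5) and MIR148B (16.7-fold, 4.30 to 144) had 3 and 2 reads in labeled libraries. Of the zinc finger genes ZNF221 fell by 1.09 ± 0.20 and ZNF202 rose by 0.76 ± 0.14. EGR1 passed at 1.95 ± 0.44 (adjusted p = 0.0211), and KLF10 was the 1 immediate early gene to fall, at -0.71 ± 0.18, a call lost with construct weights (adjusted p = 0.199, up to 0.418 over the alternatives). Spliceosomal RNAs had 8 members up, 11 adjusted over the list alone (adjusted p = 0.000367 with an estimated correlation), and immediate early genes 1 up and 1 down, 6 and 2 over the list alone, with a camera adjusted p of 0.171.

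Simulated data gave 271 false calls for PDGFR. Construct weights left 119 genes (91 higher, 28 lower) and PDGFR libraries fitted alone left 15. These fits also recovered fewer simulated 2-unit changes, 54% and 10% against 77%, so the genes lost need not be false calls. RNU4-2 and RNVU1-29 were both called with construct weights (adjusted p = 0.000344), and EGR1 was not (adjusted p = 0.0771, up to 0.474 over the alternatives). RNU6-681P, RNA5SP219 and HEXIM1 were called in 11, 12 and 17 of 38 alternatives.

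**Figure D2:**
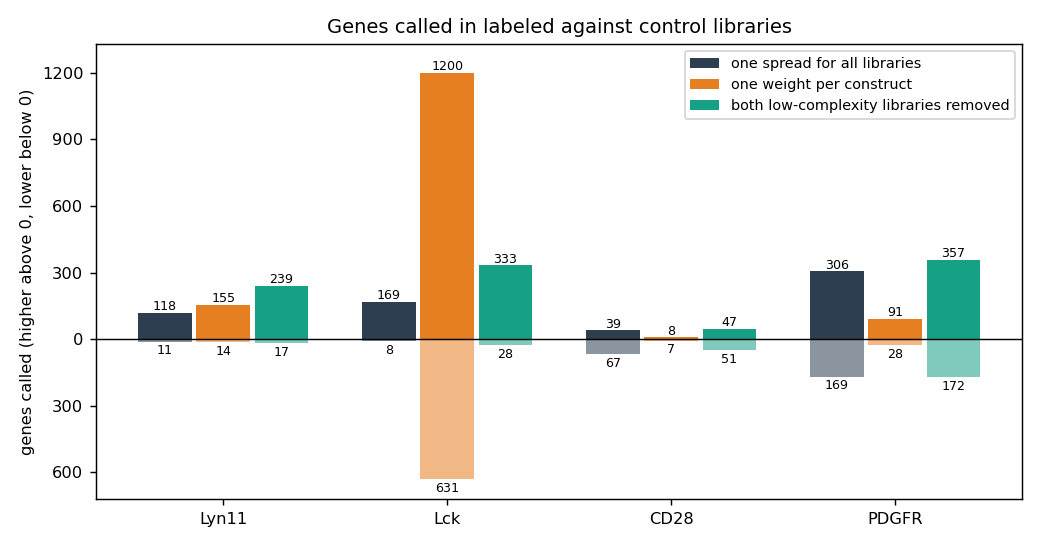
Number of genes called higher (bars above 0) and lower (bars below 0) in each construct with a spread shared by all libraries, with construct weights, and without both low-complexity libraries. Weights raise Lck from 169 and 8 to 1200 and 631 and lower PDGFR from 306 and 169 to 91 and 28.

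Across all constructs, 20 genes were higher in each of the 4, against 2.15e-05 from independent lists, and 0 lower, against 9e-08. The controls are separate for each construct. U1 genes and U1 pseudogenes were most frequent, with RNU1-1 at 3.97 ± 0.29 on average, RNU1-2 at 3.95 ± 0.27, RNVU1-29 at 3.07 ± 0.15, RNVU1-15 at 2.80 ± 0.16, RNVU1-34 at 2.53 ± 0.18, and RNVU1-21, RNU1-28P and RNVU1-27 at 2.23 to 2.47. RNU1-2 lies within CROCC, RNVU1-29 opposite a pseudogene, ENSG00000276216 overlaps RNVU1-14, ENSG00000262202 overlaps the U3 gene SNORD3D, and ENSG00000270022 (chromosome 22, 42615244 to 42615907) overlaps RNU12, the U12 RNA of the minor spliceosome, and rose by 3.98 ± 0.28. The remaining genes were SNORD3B-1, MIR5087, TMEM30CP, ENSG00000279951, EGR1, SNHG12, LINC01963, THUMPD3-AS1 and HEXIM1, which encodes an inhibitor of P-TEFb that binds 7SK RNA. HEXIM1 was higher by 0.79, 0.82, 0.76 and 0.63 in Lyn11, Lck, CD28 and PDGFR, and SNHG12 (chromosome 1, 28578538 to 28583132) by 1.06, 1.14, 0.97 and 1.53. With construct weights 6 were called in each construct, RNU1-1, RNU1-2, RNVU1-15, MIR5087, ENSG00000270022 and ENSG00000276216.

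Summed over near-identical copies, U1, U5 and U3 RNAs were higher in labeled libraries of every construct. U1 reads over 34 genes averaged 150.3 RPM labeled and 35.23 in controls, a log2 difference of 2.14 (2.45, 2.34, 1.798 and 1.96 in Lyn11, Lck, CD28 and PDGFR; exact permutation p = 3.57e-06, adjusted p = 1.67e-05). U5 was at 15.06 against 3.237 RPM (2.15) and U3 at 110.5 against 29.5 (2.02), with the same p. U4 rose by 0.82 (adjusted p = 2.5e-05) and U2 by 0.68 (adjusted p = 7e-05), each higher in all 4 constructs. U6, the partner of U4, had 113.2 against 131.4 RPM, a difference of -0.21 (adjusted p = 0.042), and was higher in Lck at 0.01 and lower in the other constructs. 7SL, the RNA of the signal recognition particle, and 7SK, Y, histone, U7, U11, U4atac and U6atac RNAs did not pass, at -0.18, -0.05, -0.21, -0.04, -0.10, -0.17, 0.26 and 0.28. Sums run over all genes with a family's name, 186 for U6, 148 for 7SL, 52 for 7SK and 15 for Y, pseudogene copies included. No Y gene of the fixed lists was among the genes tested. A lack of rise in these sums therefore does not show that the RNAs themselves were not enriched.

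**Figure D3:**
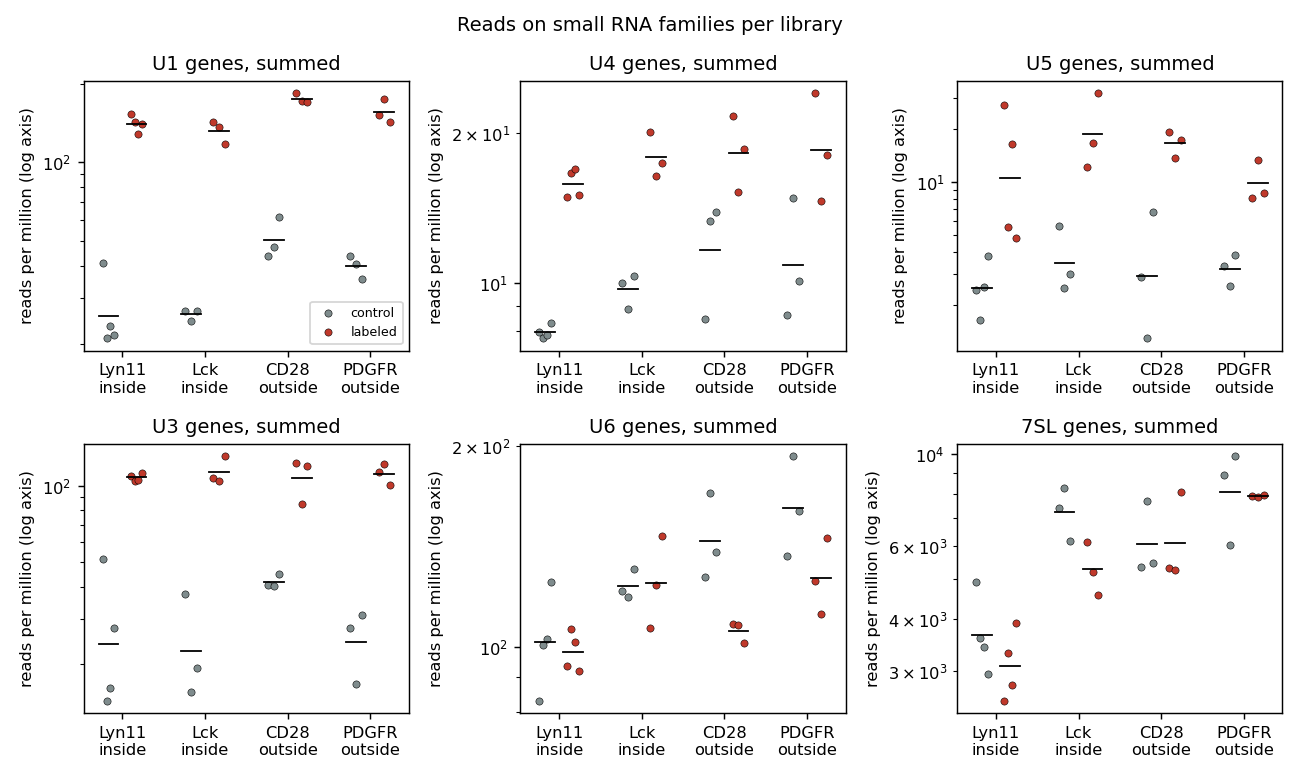
Summed RPM (reads scaled to library size) of U1, U4, U5, U3, U6 and 7SL genes in each library, on a log axis, grey for controls and red for labeled libraries, with a line at each group mean and constructs in order of side. U1 averages 150.3 in labeled and 35.23 in control libraries, while 7SL averages 5455 and 6161.

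Averaged over the constructs, 955 genes were higher and 687 lower, where simulated data gave 25 false calls. Of 13 spliceosomal RNAs 12 rose, 13 adjusted over the list alone, with a median of 2.77 and a camera adjusted p of 3.22e-29, 2.29e-05 with an estimated correlation. Beyond U1 and U4 these included RNU5B-1 at 2.89 and RNU4ATAC at 2.77. The rise of RNU4ATAC was not seen in the summed U4atac reads, which differed by 0.26 (exact permutation, adjusted p = 0.261). The small nucleolar RNA list had 4 up of 24, 3 of them U3 copies (SNORD3A 1.54 ± 0.34, SNORD3B-1 2.07 ± 0.18, SNORD3C 2.58 ± 0.29) and SNORD104 at 0.65 ± 0.18 (-0.05 with Lyn11). That list's adjusted p was 0.00958, or 0.521 with an estimated correlation, with 6 up when adjusted over the list alone. HM13-AS1 at 3.44 ± 0.38, RNVU1-4, RNVU1-6, RNVU1-18, RNVU1-31 and RNU1-27P at 2.94 to 3.34 completed the largest rises among genes with a symbol, a mean log2 of at least 1 and 1 sign in all 4 constructs. RNU6-1176P at -2.09 ± 0.22, RNU6-142P, RNU6-331P, RNU6-122P, MIR365A, RPS29P7, SNORD38D, MIR148B, RNY4P36 and MIR4505 were the largest falls among such genes, at -2.09 to -1.51, most from under 50 reads per library. SNORD38D lost its call with median centring and a stricter filter.

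Immediate early genes were 14 up and 2 down of 33 on average, 19 and 3 adjusted over the list alone. EGR1 rose by 3.09 ± 0.21 (adjusted p = 3.67e-09), FOS by 2.70 ± 0.32, FOSB by 1.78 ± 0.15, EGR3 by 1.75 ± 0.38 and CCN1 by 1.13 ± 0.13, with ARC, GADD45B, DUSP1 and JUN at 0.54 to 0.94. EGR3 passed in no single construct, at 2.496 with Lyn11, 3.06 with Lck, 2.12 with CD28, from 0 to 17 reads, and -0.68 with PDGFR (adjusted p = 0.0809 to 0.773). KLF6 fell by 0.19 and stood at 0.07 with CD28, and ZFP36L1 fell. The camera adjusted p was 3.49e-11, or 0.0978 with an estimated correlation, and fry gave 3.65e-05. FOSB overlaps ERCC1 on the opposite strand.

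Host genes of small nucleolar RNAs and other cytosolic noncoding RNAs were 4 up and 1 down of 25, 5 and 1 adjusted over the list alone. SNHG12 rose by 1.18 ± 0.08, ZFAS1 by 0.52 ± 0.07, SNHG3 by 0.34 ± 0.04 and SNHG15 by 0.33 ± 0.08, and SNHG20 fell. SNHG12, ZFAS1 and SNHG3 contain small nucleolar RNA genes on the same strand. The list's adjusted p was 0.00369, or 0.521 with an estimated correlation. THUMPD3-AS1 (chromosome 3, 9349689 to 9398579), opposite THUMPD3, rose by 0.88 ± 0.05 and was higher in all 13 labeled libraries than in any control of its construct. Nuclear-retained noncoding RNAs had 3 down of 21 and 0 up, 5 down adjusted over the list alone, with HOTAIR at -0.58 ± 0.13, AIRN at -0.76 ± 0.23 and ENSG00000231721.6 at -0.37 ± 0.09 (list adjusted p = 0.0234, or 0.475 with an estimated correlation). AIRN and HOTAIR overlap IGF2R and HOXC11 on the other strand. MALAT1, a nuclear speckle RNA, at -0.07 ± 0.13 and NEAT1, the scaffold of paraspeckles, at -0.49 ± 0.17 did not pass, nor did ACTB at 0.14 ± 0.10, GAPDH at 0.07 ± 0.09, MT-CO1 at -0.03 ± 0.20 and LYN at 0.14 ± 0.08 (adjusted p = 0.1 to 0.97).

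Differences were small among mRNAs of proteins made at the endoplasmic reticulum. Of 48 chaperones and folding enzymes 6 rose on average, the same number adjusted over the list alone, among them HERPUD1 at 0.36 ± 0.05, HSPA5, the chaperone BiP, at 0.28 ± 0.05, DNAJB9 at 0.66 ± 0.15 and CALR at 0.28 ± 0.07. The list's adjusted p was 6.8e-08, or 0.459 with an estimated correlation, and HSPA5 and CALR lost their calls with quantile normalization. Plasma membrane receptors and adhesion proteins had 2 up of 75 (EFNB2 0.34 ± 0.07, PTPRJ 0.16 ± 0.05; 1 adjusted over the list alone; adjusted p = 0.00504, or 0.766 with an estimated correlation). Plasma membrane transporters and channels had 0 of 46 (adjusted p = 0.00504, or 0.459 with an estimated correlation), and secreted and matrix proteins 2 of 47, CCN1 and TIMP3 at 0.27 ± 0.05 (adjusted p = 0.00319, or 0.766 with an estimated correlation). Inner-leaflet signalling proteins had 1 up of 40, the G protein subunit GNAI3 at 0.28 ± 0.07, and Golgi and vesicle traffic 0 of 48, neither list called (adjusted p = 0.253 and 0.223). The counts of transporters, secreted, inner-leaflet and Golgi genes were the same adjusted over the list alone.

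Among ribosomal proteins RPS9 rose by 1.04 ± 0.13 and RPS10 by 0.28 ± 0.08, of 76. RPS9 overlaps LILRB3 and other genes on both strands, and 1 member passed adjusted over the list alone. The list's median was 0.14 (adjusted p = 1.48e-05, or 0.766 with an estimated correlation). Of 13 mitochondrial mRNAs MT-ND6, the one coded on the light strand, rose by 0.86 ± 0.21, and 4 did when adjusted over the list alone (list adjusted p = 0.00504, or 0.766 with an estimated correlation). Splicing factors were 3 up (SRSF6 0.60 ± 0.08, TRA2B 0.40 ± 0.07, SRSF3) and 2 down (CLK4 -0.58 ± 0.12, DDX17 -0.20 ± 0.05) of 53, heat shock proteins 2 up of 21 (DNAJA4 1.07 ± 0.20, DNAJB1 0.33 ± 0.09), nucleolar biogenesis factors 1 up of 40 (NOP56), and proteasome subunits 0 of 30. Those lists had an adjusted p of 0.0251, 0.0109, 0.0251 and 0.00504, and none was called with an estimated correlation (adjusted p = 0.766 to 0.769). Adjusted over the list alone, NOP56 did not pass and the other counts were the same.

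The remaining lists were not called on average. The integrated stress response had 3 up and 1 down of 32, with PPP1R15A at 0.45 ± 0.07 and the mTORC1 inhibitor DDIT4 at -0.75 ± 0.12. Translation factors had 3 up of 37 (PABPC4 0.24 ± 0.05), actin and focal adhesion genes 2 up and 1 down of 51 (VCL 0.18 ± 0.05, MYL9 -0.72 ± 0.22), KRAB zinc fingers 2 up and 3 down of 104, mitochondrial ribosomal proteins 1 up of 42 (MRPS28), microtubule motors 1 down of 37 (KIF23) and cholesterol synthesis 1 down of 23 (HSD17B7). No gene passed by limma among 17 glycolysis, 48 oxidative phosphorylation, 30 oxidative stress, 46 histone and 7 fibroblast genes. Of other cell type markers, CSF1R rose by 1.17 ± 0.23 among 6 blood genes and ESRP2 by 0.98 ± 0.17 among 7 epithelial ones, both with under 400 reads per library. Adjusted over the list alone, actin genes were 3 up and 1 down and blood genes 2 up, with the other counts the same. Camera gave these an adjusted p of 0.0539 to 0.608. Only 2 members of the Y, vault, 7SL and RNase P list were measured, RN7SL2 at -0.19 ± 0.31 and RN7SL3 at -0.13 ± 0.17, so it was not tested.

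By RNA class, small nuclear RNA genes were higher more often than other genes in each construct. Of 296, 22 (7.43%, against 0.437% of other genes) were higher with Lyn11, 19 with Lck, 10 with CD28 and 27 with PDGFR (Fisher's exact test, odds ratios 18.3, 9.98, 26.4 and 7.81, adjusted p at most 1.46e-09). With PDGFR they were also lower more often, 7 of 296 or 2.37% against 0.737% (odds ratio 3.26, adjusted p = 0.0384). On average antisense genes were lower more often, 186 of 2376 or 7.83% (odds ratio 3.29, adjusted p = 5.17e-33). By construct this passed with CD28 (18 genes, adjusted p = 0.00181) and PDGFR (51, adjusted p = 3.01e-11), and not with Lyn11 (3, adjusted p = 0.382) or Lck (3, adjusted p = 0.198). CD28 and PDGFR hold the low-complexity libraries, a labeled one in CD28 and a control in PDGFR, and their part in these falls was not tested. Processed transcripts (odds ratio 3.75, adjusted p = 4.8e-05), sense intronic RNAs (2.09, 0.00124), the class TEC (2.24, 0.00223) and processed pseudogenes (1.403, 0.0163) were also lower more often on average. With CD28 the median was -0.39 for antisense genes, -0.47 for sense intronic and miscellaneous RNAs, -0.45 for microRNAs, -0.42 for small nuclear RNAs and 0.11 for protein-coding genes. With Lyn11, Lck and PDGFR the antisense median was -0.03, -0.04 and -0.02. Protein-coding genes were called less often in both directions on average, with 163 of 12936 lower (1.26% against 5.61%, odds ratio 0.215, adjusted p = 2.3e-75) and 499 higher (3.86% against 4.88%, odds ratio 0.782, adjusted p = 0.00124). Long intergenic RNAs were called more often in both, with 104 of 1279 higher and 71 lower (odds ratios 2.1 and 1.95). By construct the first passed with Lck, CD28 and PDGFR (adjusted p = 0.0486, 0.0105 and 0.0384) and the second in none of the 4. Genes are not independent replicates.

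The constructs were then compared with each other. Lyn11 and Lck shared 92 higher genes, against 0.895 from independent lists, and their differences correlated across genes at Pearson 0.69 and Spearman 0.48. Opposite sides shared 71 (Lyn11 and PDGFR, 1.62 expected), 81 (Lck and PDGFR, 2.32), 27 (Lyn11 and CD28, 0.207) and 29 (Lck and CD28, 0.296), and CD28 and PDGFR shared 27 (0.536 expected), with Pearson 0.40, 0.41, 0.29, 0.31 and 0.20. Lower genes were shared by 1 to 10, with 10 in CD28 and PDGFR against 0.508 (Fisher's exact test, adjusted p = 1.1e-10). Genes are not independent replicates.

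**Figure D4:**
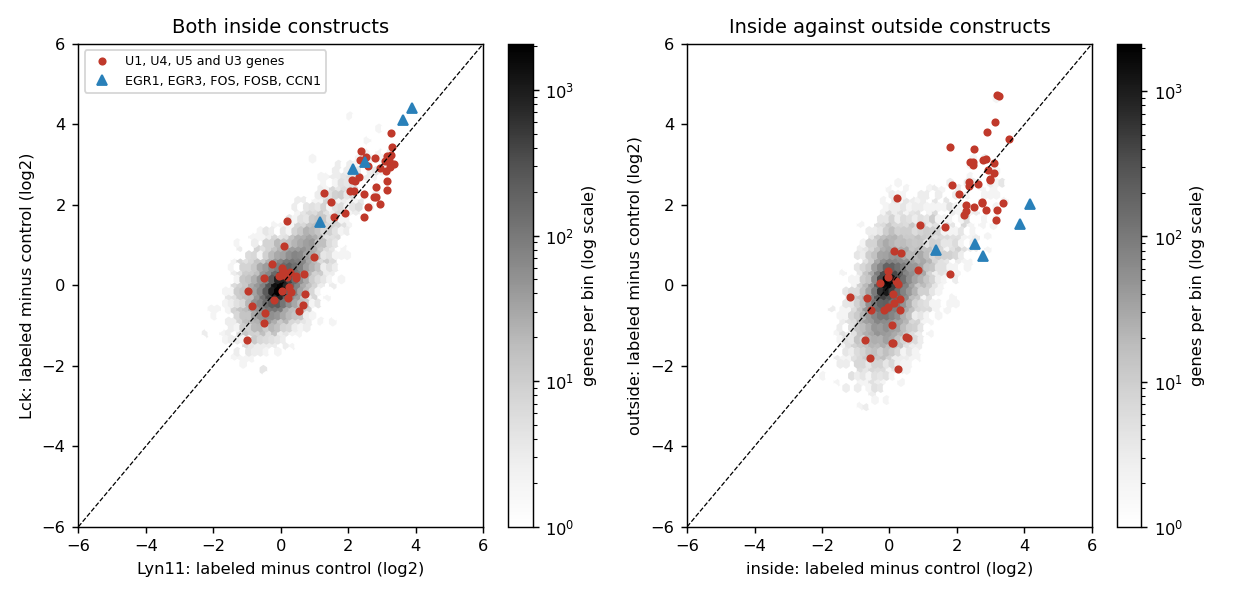
Log2 difference between labeled and control libraries of each tested gene, Lyn11 against Lck and inside against outside, with shading for genes per bin on a log scale and a dashed line of equality. Red points are U1, U4, U5 and U3 genes, and blue triangles are EGR1, EGR3, FOS, FOSB and CCN1, with EGR1 at 4.16 inside and 2.02 outside.

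Inside constructs had 555 higher and 82 lower genes and outside constructs 340 and 370, where simulated data gave 0 and 133 false calls. EGR1 rose by 4.16 ± 0.29 inside and 2.02 ± 0.31 outside and FOSB by 2.53 ± 0.21 and 1.03 ± 0.22. FOS rose by 3.87 ± 0.43 inside and stood at 1.53 ± 0.46 outside, which did not pass (adjusted p = 0.0753). The differences between sides were 2.14 ± 0.42 for EGR1, 2.34 ± 0.63 for FOS and 1.499 ± 0.31 for FOSB, none past the threshold over all genes (adjusted p = 0.345 to 0.576). Immediate early genes were 12 up of 33 inside (19 up and 2 down adjusted over the list alone) and 5 up outside (9 up and 1 down adjusted over the list alone). Between sides 0 passed over all genes and 5 were higher and 1 lower adjusted over the list alone, with a list adjusted p of 1.85e-06, or 0.315 with an estimated correlation. Spliceosomal RNAs had 10 up inside and 12 outside (13 and 12 adjusted over the list alone), with medians of 2.502 and 3.09, and the list did not differ between sides (adjusted p = 0.113).

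Directly compared, 1 gene was called between the sides, where simulated data gave 13 false calls. The fit recovered 72% of simulated 2-unit changes and 37% of 1-unit changes, so differences between the sides can be missed. RNU6-1176P (chromosome 1, 65022968 to 65023074), a U6 copy, was higher inside by 3.03 ± 0.44 (adjusted p = 0.0197), with differences of -0.79, -0.36, -3.30 and -3.91 in Lyn11, Lck, CD28 and PDGFR, from at most 25 reads per library. Construct weights ended the call (adjusted p = 0.175, up to 0.616 over the alternatives), with 0 genes called by limma and 0 by limma voom, and 1453 genes had an unadjusted p under 0.05. Of 31 lists 19 were called between sides by camera, 2 higher and 17 lower inside, and 0 with an estimated correlation or by fry. Cytosolic ribosomal proteins, with a median of -0.42, were among them (adjusted p = 4.63e-18, or 0.315 with an estimated correlation). Fitted on their own libraries, outside constructs had 65 genes called and inside ones 1475. The inside split was 87.1% higher, or 75.4% with quantile normalization and 71.7% with construct weights. With library weights, which did not converge, most calls were lower, with 43.1% higher inside (3022 higher, 3983 lower), 46.8% in Lyn11 and 45.5% in Lck. The outside split was 47.9%, or 60.5% with median centring (475 higher, 310 lower), which moved the outside median of all genes to 0.10, and 60.4% without both low-complexity libraries.

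Within sides, no gene differed between Lyn11 and Lck by limma, with 71 at an unadjusted p under 0.05, 0 by limma voom and 0 with construct weights. Limma recovered 58% of simulated 2-unit changes and 13% of 1-unit changes in this comparison, and 79% and 43% with construct weights. Its 0 therefore does not show that the 2 constructs are alike. CD28 and PDGFR differed in 11 genes, 1 higher and 10 lower with CD28, among them RGS17P1 at -6.48 ± 0.67 and the 7SL copies RN7SL502P and RN7SL306P at -6.63 ± 0.89 and -6.09 ± 0.77. Simulated data gave 120 false calls for this comparison, and construct weights left 3 genes, among them RGS17P1 and RN7SL306P. Limma voom called 0, with 2079 genes at an unadjusted p under 0.05 in limma.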

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

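Of the tests in this part, those of other short genes and of nuclear-retained RNAs were chosen after the results they bear on were seen. The family sums and the removal of both low-complexity libraries, also used here, were chosen after seeing the data.

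In the groups of 4, which only Lyn11 has, 72 measures were tested with Dixon's criterion and 6 values in 2 libraries stood apart, where chance picks about 1 in 20 groups. Lyn11 control replicate 1 had 5 of them, 239 genes at 0 reads (103 to 112 in the other controls) and log2 values of 3.857 for RNVU1-29 (others 2.703 to 2.792), 4.721 for RNVU1-15 (3.293 to 3.525), 4.557 for ENSG00000262202 (2.874 to 2.908) and 1.71 for NCLP1 (2.005 to 2.058). Lyn11 labeled replicate 3 had SNHG12 at 4.397 (others 4.754 to 4.77). U1 and U3 gene values in that control lay toward those of labeled libraries, and no explanation was tested.

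Some differences between constructs passed a test of the difference itself. RNU6-1176P differed by 3.0279 between inside and outside. Between CD28 and PDGFR the log2 differences were -6.6305 for RN7SL502P, -5.2155 for FDPSP2, -6.0939 for RN7SL306P, 3.3478 for ENSG00000253426.5, -6.0657 for ENSG00000219928, -5.7455 for ALG9-IT1, -6.0471 for ENSG00000257346, -6.4779 for RGS17P1, -3.329 for ENSG00000265625, -6.3791 for LINC01730 and -6.5375 for ENSG00000207380.1. With construct weights RN7SL306P, RGS17P1 and ENSG00000207380.1 kept an adjusted p under 0.05 (0.00989, 0.00073 and 0.00404), as they did without both low-complexity libraries (1.35e-05, 0.000547 and 0.00688). RNU6-1176P lost its limma call with construct weights (adjusted p = 0.175) and kept it without both low-complexity libraries (0.0256). Simulated data gave 13 false calls for inside minus outside and 120 for CD28 minus PDGFR. Limma voom called no gene in either, so these calls may be false.

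Pattern 1 was the rise of U1, U4, U5 and U3 RNAs. Other tested genes under 300 bp, 1613 of them, had a median difference of -0.1032, against a gain of reads on all short genes. Some short genes, such as MIR93 within MCM7, lie inside longer genes whose reads they may hold. This median therefore does not decide whether short RNA molecules gained. U1 reads summed over 34 genes, which sharing among those genes cannot move, still differed by 1.7978 in the construct where they differed least. Loss of reads to copies outside these genes was not tested. The spliceosomal list had a median of 2.9929 without both low-complexity libraries. As the whole cause for U1, these values exclude a gain of reads on all short genes, sharing among the summed copies, and the low-complexity libraries. Summed U5 and U3 reads rose by at least 1.61 and 1.35 in each construct, and summed U4 reads by 0.65 to 0.99. Sharing between copies therefore stays open for the larger rises of single U4 genes. A hypothesis is that labeling itself enriched these RNAs. The data may not tell tagging at the membrane from tagging elsewhere, since no other compartment was labeled in the libraries analysed here. A change in total RNA during labeling was not tested for these RNAs and stays open, because unenriched RNA was not analysed here.

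Pattern 2 was the rise of immediate early mRNAs. Nuclear-retained RNAs had a median of -0.1736 and a highest value of 0.22, which argues against a gain shared by all nuclear RNA. The list's own fall was lost with an estimated correlation (camera adjusted p = 0.0234, then 0.475). U1, U5 and U3, which are nuclear too, rose by 2.14, 2.15 and 2.02, so a gain of part of the nuclear RNA stays open. Without both low-complexity libraries 14 immediate early genes were called higher on average, and with all libraries 14 were. A change in total RNA during labeling, for example induction by fresh medium or peroxide if controls did not get them, could raise such genes too. Such a change cannot be told apart from enrichment, because unenriched RNA was not analysed here and the step omitted from controls is not known. An effect of the construct's site stays open as well.

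Pattern 3 was the split of calls, mostly lower with CD28 (36.8% higher) and mostly higher with PDGFR (64.4% higher). These percents lay 27.6 points apart, and 19.5266 without both low-complexity libraries, inside the 10 to 20 points for which the test decides nothing. With quantile normalization they were 58.7% and 60.2%. With single libraries left out they ran from 15.5% (without CD28 labeled replicate 3) to 54.8% (without CD28 control replicate 1) and from 47.5% (without PDGFR labeled replicate 1) to 72.8% (without PDGFR control replicate 1). The scaling, single libraries, the low-complexity libraries and a difference between constructs all stay open.

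Other splits of the libraries gave these results. Chance is excluded for Lyn11 calls (129, highest other of 35 splits 4), and among 100 drawn relabelings for the average (1642, highest other 6), inside (637, 0), outside (710, 223), genes called in all 4 constructs (20, 0), and the camera p of the spliceosomal (as -log10, 29.98 against 12.41) and immediate early lists (11.65 against 9.223). Splits are too few for a share under 0.05 for Lck (177, highest other 0), CD28 (106, 23) and PDGFR (475, 122), where 10 splits exist. Chance is not excluded for the number of lists called on average (15, 25 of 100, highest 23). For inside minus outside (1 called, 32 of 100 relabelings as many, highest other 9), Lyn11 minus Lck (0, all 100, highest 437) and CD28 minus PDGFR (11, 55 of 100, highest 86) the relabelings decide nothing, because one that keeps more of the labels in one construct than in another turns the labeling effect itself into a difference between constructs. The 100 relabelings are a draw from 560000, and the highest other depends on the draw and gives no margin. In another draw it was well above these values for the average and for inside, with the same outcome for each result. For inside alone it lay closer to the real count than to 0.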

How the results depend on the processing

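The 10-read filter, limma voom, the removal of both low-complexity libraries and construct weights were chosen after seeing the data. Of 293 named gene results 245 were called, 119 of them in every alternative that gave a value (up to 38) and 126 lost in at least 1, with 0 changes of sign. The stricter filter tested 15129 genes and voom 25597, against 22284 in the other settings below, and the cause of the differences between the counts below was not tested. Depth, spread and complexity differ together with side, so the part of depth was not tested. Depth limits the genes at 0 or few reads, whose folds are bounds or carry wide counting intervals, such as 13.1 to 3005 for RNU1-2 with CD28.

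Lyn11 (129 genes) had 256 with quantile normalization, 74 with a stricter filter, 3332 with library weights, 229 with voom and 256 without both low-complexity libraries. Lck (177) had 484 with quantile normalization, 296 with a pseudocount of 1 FPKM, 74 with a stricter filter, 6676 with library weights, 1831 with construct weights, 340 with voom, 361 without both low-complexity libraries and 984 on its own libraries. CD28 (106) had 63 with quantile normalization, 64 with a stricter filter, 15 with construct weights, 21 with voom and 0 by limma on its own libraries, where 1525 had an unadjusted p under 0.05 and 26% of simulated 2-unit changes were recovered. PDGFR (475) had 130 with a stricter filter, 217 with library weights, 119 with construct weights, 132 with voom and 15 on its own libraries, where 10% were recovered. The average (1642) had 727 with a stricter filter and 3206 with library weights. Library weights did not converge and put up to 10.65 on a single library (Lck control replicate 3), so their counts rest on few libraries, and they turned most calls of Lyn11, Lck and inside to lower (46.8%, 45.5% and 43.1% higher).

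Inside (637) had 1093 with quantile normalization, 255 with a stricter filter, 7005 with library weights, 1616 with construct weights, 1169 with voom, 959 without both low-complexity libraries and 1475 on its own libraries. Outside (710) had 313 with a stricter filter, 215 with construct weights, 372 with voom and 65 on its own libraries. Inside minus outside (1) had 4 with quantile normalization, 4 with a pseudocount of 1 FPKM, 11 with library weights, 8 without both low-complexity libraries, and 0 with construct weights or voom. Lyn11 minus Lck (0 by limma, 71 unadjusted) had 78 with library weights. CD28 minus PDGFR (11) had 5 with quantile normalization, 1 with a stricter filter, 3 with construct weights, 24 without both low-complexity libraries, and 0 with voom or on its own libraries. Genes called in every construct (20) were 35 with a pseudocount of 1 FPKM, 31 with library weights, 6 with construct weights, 12 with voom and 0 on own libraries, which the 0 of CD28 fixes.

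Replicate numbers did not pair the libraries. Deviations of same-numbered labeled and control libraries correlated at -0.288 to 0.166 over 13 pairs, and 3 of 13 had their own number as best partner (replicate 2 of Lyn11, Lck and CD28). With a replicate block the counts were 60 for Lyn11, 64 for Lck, 29 for CD28, 290 for PDGFR, 453 for outside, 0 for inside minus outside, 2 for CD28 minus PDGFR, 11 in every construct, and 6 lists for PDGFR.

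Of the list tests, an estimated correlation left 2 of 7 lists for Lyn11, 2 of 10 for Lck, 1 of 22 for CD28, 1 of 3 for PDGFR, 1 of 15 on average and 0 of 19 for inside minus outside, and fry called 2, 2, 1, 1, 7 and 0. Quantile normalization left 7 for CD28 and 11 for inside minus outside, and removal of both low-complexity libraries left 1 for PDGFR. The endoplasmic reticulum chaperone list reversed between sides with quantile normalization, with a median of 0.0699 (adjusted p = 0.0239) against -0.11.

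With each library left out the counts were 71 to 179 for Lyn11, 74 to 244 for Lck, 42 to 464 for CD28, 334 to 727 for PDGFR, 1293 to 1781 on average, 438 to 780 inside, 485 to 873 outside, 0 to 6 for inside minus outside, 0 to 0 for Lyn11 minus Lck, 9 to 111 for CD28 minus PDGFR and 14 to 29 in every construct. Lyn11 had 71 and 75 without labeled replicates 2 and 4, and 77, 73 and 75 without controls 2, 3 and 4. Lck had 74, 81 and 82 without labeled replicates 1, 2 and 3 and 76, 82 and 101 without its controls. CD28 had 464, 45 and 206 without labeled replicates 1, 2 and 3, 42, 56 and 60 without its controls, and 165 without PDGFR control 2. PDGFR had 727 without its control 1. Inside minus outside had 0 without Lyn11 labeled 4, Lck controls 2 or 3, CD28 labeled 2 or PDGFR labeled 2, 5 and 3 without CD28 labeled 1 and 3, 2 without CD28 control 2 or PDGFR labeled 1 or 3, and 6, 4 and 4 without PDGFR controls 1, 2 and 3. CD28 minus PDGFR had 79 and 20 without CD28 labeled 1 and 3, 22 and 23 without PDGFR labeled 1 and 2, and 111, 20 and 105 without PDGFR controls 1, 2 and 3. All other left-out libraries moved these counts by under 1.5 times.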

Other observations

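Both tests of neighbouring genes were chosen after tissue-restricted genes had been seen among the calls, and before their own results were known. The genes named in this part were chosen after their values were seen.

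Coding genes that HEK293T cells hardly express were among those higher on average. IL17C, an epithelial cytokine, rose by 2.95 ± 0.49, HK3, the hexokinase of myeloid cells, by 2.95 ± 0.53, and ACTA1, skeletal muscle actin, by 2.11 ± 0.20. FAM83E rose by 2.81 ± 0.49. Each lies downstream of an expressed gene on the same strand that was not called. IL17C starts 6625 bp past ZC3H18 (0.06), HK3 5673 bp past UIMC1 (-0.10), ACTA1 6162 bp past NUP133 (0.04) and FAM83E 474 bp past RPL18 (0.18).

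A hypothesis is that reads of such genes may come from transcription past the ends of their neighbours. Of 335 coding genes higher on average with a mean log2 under 2, 69 or 20.6% had a same-strand gene with a mean log2 of at least 3 ending within 10 kb upstream. Among 10000 lists of genes not called and matched on level the median was 8.36% and the upper end of their central 95% 11.34% (permutation p = 0.0001, the smallest these lists can give). Location in gene-dense regions predicts the same excess downstream. There 7.463% had an expressed same-strand neighbour starting within 10 kb, against a median of 5.97% and an upper end of 8.358% for matched lists (permutation p = 0.134). The smaller excess argues against density on the same strand as the whole cause, and a part of it stays open. Matching was on level alone, and neighbours on the opposite strand were not counted. The 69 genes had a median difference of 0.99 and their neighbours 0.03, with 2 neighbours called higher, JUND and RABGGTB. Inside constructs alone gave 20.59% (49 of 238). A change in total RNA during labeling, RNA still bound to chromatin and DNA in the libraries were not tested and stay open.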
